A study of Mus musculus with 62 samples.

How the data were processed

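RNA of the tibialis anterior muscle had been sequenced from 62 libraries in 12 groups, given by treatment and week. Libraries were made with a stranded mRNA kit of Illumina and read on a NovaSeq instrument, per the labels' protocols. The authors deposited 1 table of TPM, transcript shares scaled to a fixed total, with 47643 gene symbols, and each of its 62 columns sums to 1000000. The genome build is mm10 per the submitters' processing notes, while the aligner, the counter, the annotation and any filter are not given in the sources used here. Because TPM fixes the total of each library, a lower share of abundant transcripts raises the values of all other genes in that library. Reads shared by near-identical genes, such as histone copies, major urinary proteins, serpins and immunoglobulin constant regions, were divided in a way that is not given, so the values of such genes are uncertain. Every column was matched to a sample by its title, and 0 columns were left unmapped.

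TPM keeps no read depth. The depth was estimated from the steps between low values with exon lengths of GENCODE M21 (GRCm38, the same assembly as mm10), which gave 47 to 55 times 1000000 reads per library with a median of 49.4 times 1000000. Of the values between 0.5 and 5 estimated reads, 83.1% were whole within a tolerance of 0.05 reads. Because lengths were available for 10769 of the 11107 genes kept and over 95% of values were whole in 6779 of them, this was used only as a guide to depth and no count test was run. The median gene kept had a mean of 849 estimated reads, and the lower quartile was 326 reads, so counting error was small beside the spread between libraries. Among 131 pairs of libraries of the same group, the closest pair differed by 5.39 times counting noise, so no library was counted as a duplicate.

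Values were transformed as log2(TPM + 1), and genes with a mean of at least 1 TPM over all libraries were kept, 11107 of the 23019 with any value above 0. All 62 libraries entered 1 linear model with a mean for each group, fitted with limma 3.58.1 in R 4.3.3 with empirical Bayes moderation and a mean-variance trend (50 residual degrees of freedom). The spread of a gene was taken as equal in all groups. Where CAC libraries varied more than the others, SE and p are therefore too small for comparisons with CAC and too large for NCAC against mock muscle. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each of 15 contrasts. Log2 changes are on the log2(TPM + 1) scale, which understates the change of weakly expressed genes. Folds are ratios of mean TPM. Of 41 lists, 28 of pathways and 13 of cell types, those with at least 3 tested genes entered limma's camera, which left out the lymphocyte, melanocyte and keratinocyte lists, with the correlation between genes estimated from the residuals and two-sided p adjusted over the lists tested in a contrast. Beside each list stand its called members and the number adjusted over the list alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for depth and plots.

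The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule selects, per contrast, the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 TPM in the higher group and a symbol that is not of a predicted gene, clone or pseudogene, up to 4 called members of each list with the smallest adjusted p, and a panel of 12 genes (Fbxo32, Trim63, Mstn, Myh4, Myh2, Pdk4, Mt2, Socs3, Cdkn1a, Fkbp5, Ppargc1a and Fst). The text draws its genes from those this rule selects and does not print all of them, and the result of 1 gene called at 2 weeks is not reported here. The alternatives were a pseudocount of 0.1, no filter, rescaling by median-of-ratios size factors (0.613 to 1.47), a fit with only the groups of the compared weeks, the replicate number as a block, each library left out in turn, and a preset correlation of 0.01 in camera. Added after seeing the data were fits without the mitochondrially encoded genes, without the 3 libraries farthest out on the first principal component, without the libraries holding more than 100 TPM of albumin, and without CAC libraries.

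The model was tested on simulated data with known changes in the layout of 5 of the contrasts. In the layout of CAC against mock at 8 weeks, 59.7% of genes changed by 0.5 on the log2 scale were called, 92.5% of those changed by 1, and 10 of 10907 unchanged genes were called. In the layout of NCAC against mock at 6 weeks, 47.8% and 89.6% were called, with 19 unchanged genes. The simulated noise was independent between genes and equally wide in all groups, as the model assumes. These rates therefore do not carry over to genes that vary together or groups of unequal spread. The titles give each library a distinct number, and the protocols call the libraries biological replicates, while the labels give no sequencing batch. Each library was taken to come from a different mouse, which the titles do not state. The strain is C57BL6/J in the sample labels and athymic nude in the design text, and this was left open. The extraction protocol of every sample names another time point, 3 weeks, and another tumour, LLC cells, which no title or treatment label does, and the weeks of titles and labels were used.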

Results

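Gene expression was profiled in the tibialis anterior, a mainly fast-twitch muscle of the hind limb, of female mice aged 2 months during the development of cachexia, the wasting of muscle and fat that accompanies many cancers. Mice had received melanoma cells called cachectic (CAC), melanoma cells called non-cachectic (NCAC) or a mock injection (Con), and muscles were taken 2, 4, 6 and 8 weeks later. Each of the 12 groups held 5 libraries, except CAC at 8 weeks with 7. The numbers in the titles run without gaps in the other groups but with gaps in CAC at 8 weeks. No reason is given, so whether these 7 are all the muscles of that group is not known. Estimated depth was similar between libraries. The first principal component of log2(TPM + 1) held 49.7% of the variance and the second 8.05%. Spearman correlations between libraries lay between 0.854 and 0.989.

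The first question was how early the muscle of CAC mice departs from mock muscle. At 2 weeks 6 genes rose in CAC muscle and none fell. Stat3, the transcription factor activated by interleukin-6 family receptors, was 1.97-fold higher (20.6 ± 4.65 against 10.4 ± 1.51 TPM, SD, n = 5 in each group). Socs3, the feedback inhibitor of that pathway, was 3.85-fold higher with a wide spread (6.15 ± 4.76 TPM against a mean of 1.60 TPM). Jak3, a tyrosine kinase of cytokine receptors, was 2.43-fold higher (7.91 ± 1.67 against 3.26 ± 0.734 TPM), and Trim72, a membrane repair protein of muscle, averaged 203 ± 34.2 against 101 ± 14.5 TPM. Tmem176b, a membrane protein of immune cells, rose as well. By limma, the log2 change was 0.99 (SE 0.14, adjusted p = 3.82e-05) for Trim72 and 1.06 (SE 0.17, adjusted p = 0.000214) for Jak3, both higher than the mock mean in 5 of 5 libraries. It was 0.90 for Stat3 (adjusted p = 0.0118, 5 of 5), 0.97 for Tmem176b (adjusted p = 0.024, 5 of 5) and 1.24 for Socs3 (adjusted p = 0.0306, 4 of 5). Of 25 tested genes of interleukin-6 family signalling and the acute phase, 2 rose (4 higher and 2 lower when adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.946 with an estimated correlation). The muscle ubiquitin ligase Trim63 stood at 134 ± 26.7 against 120 ± 18.9 TPM (adjusted p = 0.916). After rescaling, 6 genes were higher and 6 lower. A fit of this week alone called 3 genes and the replicate number as a block gave 4, all of them among the 6 of the main fit. Without CAC replicate 3, 4 or 5, 2 genes were called in each case and the calls of Stat3, Socs3 and Tmem176b ended (adjusted p = 0.124, 0.0718 and 0.102 for Stat3, 0.299, 0.104 and 0.142 for Socs3 and 0.195, 0.16 and 0.142 for Tmem176b). The count was 10, all higher, without CAC replicate 1 and 16 (9 higher and 7 lower) without CAC replicate 2. Without mock replicates 3, 4 and 5 it was 37 (9 higher and 28 lower), 11 (6 and 5) and 24 (4 and 20). The call of Socs3 also ended without mock replicate 1 (adjusted p = 0.09). The call of Tmem176b ended without mock replicate 2 (adjusted p = 0.063) or 5 (adjusted p = 0.052).

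At 4 weeks the same signalling genes were further apart. Socs3 was 12.2-fold higher in CAC than in mock muscle (20.6 ± 6.77 against 1.69 ± 0.27 TPM, SD, n = 5 in each group), Stat3 was 2.73-fold higher (30.1 ± 3.84 against 10.99 ± 1.22 TPM). The oncostatin M receptor gene Osmr was 2.98-fold higher (4.30 ± 2.04 against 1.44 ± 0.192 TPM). Apod, a lipid-binding apolipoprotein, was 3.45-fold higher, Csf2rb, a shared subunit of cytokine receptors, 4.53-fold, and Atp9a, a membrane lipid flippase, 3.02-fold. Among the decreases, Grb14, an adaptor that restrains the insulin receptor, fell by 0.84 on the log2 scale, and Msra, which repairs oxidised methionine, fell by 0.41. By limma 99 genes rose and 5 fell. The adjusted p was 5.35e-12 for Socs3 (log2 change 2.96, SE 0.26), 1.5e-08 for Atp9a (1.51, SE 0.17), 3.25e-07 for Stat3 (1.37, SE 0.17), 1.97e-06 for Csf2rb (1.52), 1.82e-05 for Osmr (1.05) and 0.00066 for Apod (1.62), each higher in 5 of 5 libraries. It was 0.0208 for Grb14 and 0.018 for Msra, each lower in 5 of 5.

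In the interleukin-6 and acute-phase list, 8 of 25 genes rose at 4 weeks (15 adjusted over the list alone, 8 after rescaling), among them Bcl3 (log2 change 1.02, adjusted p = 6.69e-05). The list did not pass camera as deposited (adjusted p = 0.104 with an estimated correlation), but it did after rescaling (adjusted p = 0.0354) and without the libraries with over 100 TPM of albumin (adjusted p = 0.0356, chosen after seeing the data). Of 58 cytosolic ribosomal protein genes, 2 were called higher (51 adjusted over the list alone, none after rescaling, adjusted p = 0.417 with an estimated correlation). No gene of the tricarboxylic acid cycle was called over all genes, while 8 of 21 were lower when adjusted over the list alone (adjusted p = 0.0901 with an estimated correlation). Metallothionein Mt2 averaged 453 ± 573 TPM (298 and 294 without CAC replicates 2 and 4) against 16.2 ± 15.1 TPM (9.80 without mock replicate 5) and was not called (log2 change 3.21, adjusted p = 0.0635, higher in 4 of 5). Trim63 (402 ± 372, or 246 without CAC replicate 2, against 147 ± 36.5 TPM, adjusted p = 0.38) and Fbxo32 (175 ± 139 against 76.7 ± 20.5 TPM, adjusted p = 0.437) were not called either. CAC replicates 2 and 4 decided much of the count, which was 38 without either, 241 without CAC replicate 1, and 61 and 55 without mock replicates 2 and 4. Without CAC replicate 2 the call of Grb14 (adjusted p = 0.26) and of Msra (adjusted p = 0.12) ended, as it did without CAC replicate 4 (0.18 and 0.17) and for Grb14 without mock replicates 2 and 4 (0.086 and 0.085) and for Msra without mock replicate 3 (0.059). In contrast, Mt2 was called without CAC replicate 1 (0.018), CAC replicate 5 (0.00891) or mock replicate 5 (0.047). After rescaling 98 genes were higher and 68 lower.

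**Figure D1:**
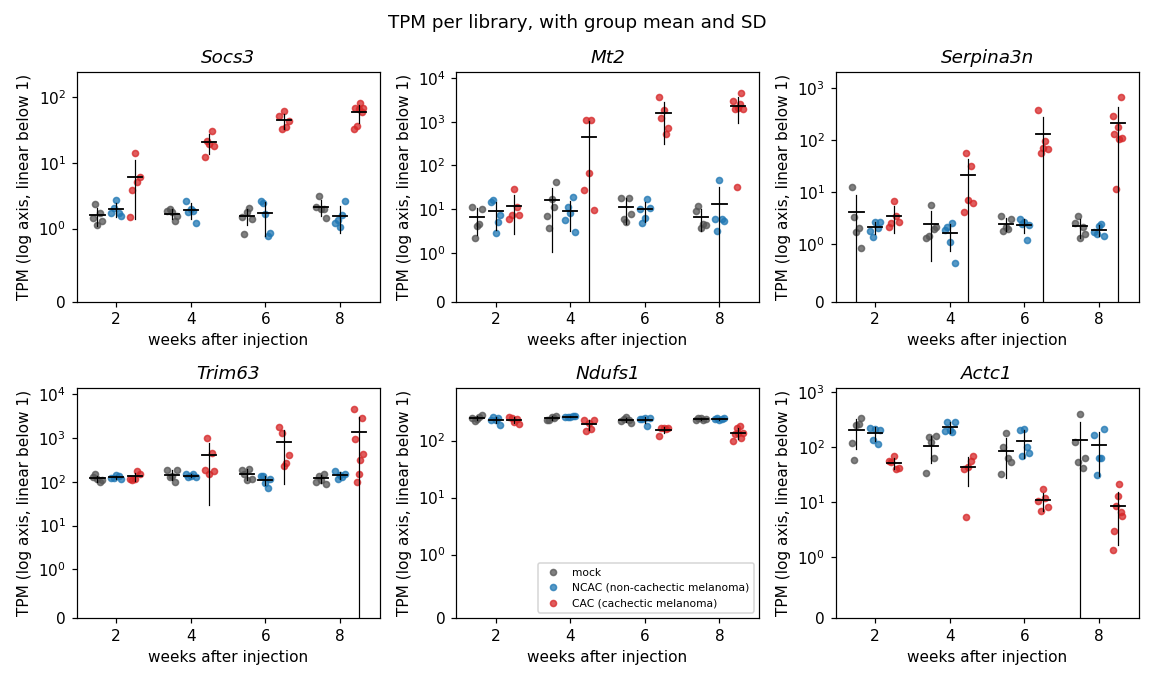
TPM of Socs3, Mt2, Serpina3n, Trim63, Ndufs1 and Actc1 by week after injection, on a log axis that is linear below 1 TPM, with each point a library, the bar the mean and the line the SD of mock, NCAC and CAC muscle. Socs3 in CAC muscle averages 6.15 TPM at 2 weeks, 20.6 at 4, 44.5 at 6 and 58.7 at 8 weeks, Actc1 averages 51.0 TPM at 2 weeks and 8.32 at 8 weeks, and the directions of these genes at 8 weeks hold after rescaling.

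At 6 weeks limma called 7103 of 11107 genes between CAC and mock muscle as deposited and 3886 after rescaling. Mt2, which binds zinc and copper, reached 1596 ± 1283 against 11.2 ± 6.66 TPM (SD, n = 5 in each group), and the acute-phase genes Hp (haptoglobin), Serpina3n and Lcn2 were 51.2-, 54.2- and 207-fold higher. Without CAC replicate 1 the fold was 29.2 for Serpina3n and 90.04 for Lcn2, and for Hp it was 31.2 without CAC replicate 4 and 119 without mock replicate 5. Fkbp5, a glucocorticoid-induced chaperone, was 9-fold higher, and C4b, a complement component, 18.3-fold. The decreases were led by Actc1, the cardiac and fetal actin, at 10.7 ± 3.91 against 84.5 ± 57.2 TPM, followed by the muscle-secreted peptide Ostn and by Nrep, Cyfip2 and Lrtm1. Fabp3, the muscle fatty acid carrier, was at 409 ± 10.6 against 1175 ± 239 TPM. By limma the log2 change was 6.86 for Mt2 (SE 0.89, adjusted p = 2.65e-08), 5.02 for Hp (adjusted p = 1.62e-07), 4.87 for Serpina3n (adjusted p = 1.67e-09), 4.85 for Lcn2 (adjusted p = 1.72e-08), 4.14 for Socs3 (SE 0.26, adjusted p = 3.81e-18), 3.37 for C4b (adjusted p = 1.99e-09) and 3.01 for Fkbp5 (adjusted p = 6.32e-05), each higher in 5 of 5 libraries. It was -2.69 for Actc1 (SE 0.56, adjusted p = 8.55e-05), -2.19 for Ostn (adjusted p = 0.00011), -2.15 for Nrep (adjusted p = 7.45e-05), -1.97 for Cyfip2 (adjusted p = 0.000329), -1.70 for Lrtm1 (adjusted p = 5.98e-05) and -1.49 for Fabp3 (adjusted p = 1.02e-06), each lower in 5 of 5.

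By count, 6741 genes were higher and 362 lower in CAC muscle at 6 weeks, and 7707 and 565 at 8 weeks, which is 94.9% and 93.2% higher. The median log2 change of all 11107 genes was 0.38 and 0.46, so most small increases lay near a shift common to all genes. After median-of-ratios rescaling, which centres the genes by construction, 1872 were higher and 2014 lower at 6 weeks and 2761 and 2690 at 8 weeks. At 8 weeks 2761 genes were higher and 565 lower under both scalings and 381 changed direction, against 59 at 6 weeks. Most list counts are therefore given below both as deposited and rescaled, and so are the values of some genes. The shift went with a lower share of abundant transcripts, since mitochondrially encoded genes held 38.6 ± 3.39% of TPM in CAC against 47.9 ± 2.74% in mock muscle at 6 weeks and 37.7 ± 2.43% (n = 7) against 48.8 ± 7.08% at 8 weeks.

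**Figure D2:**
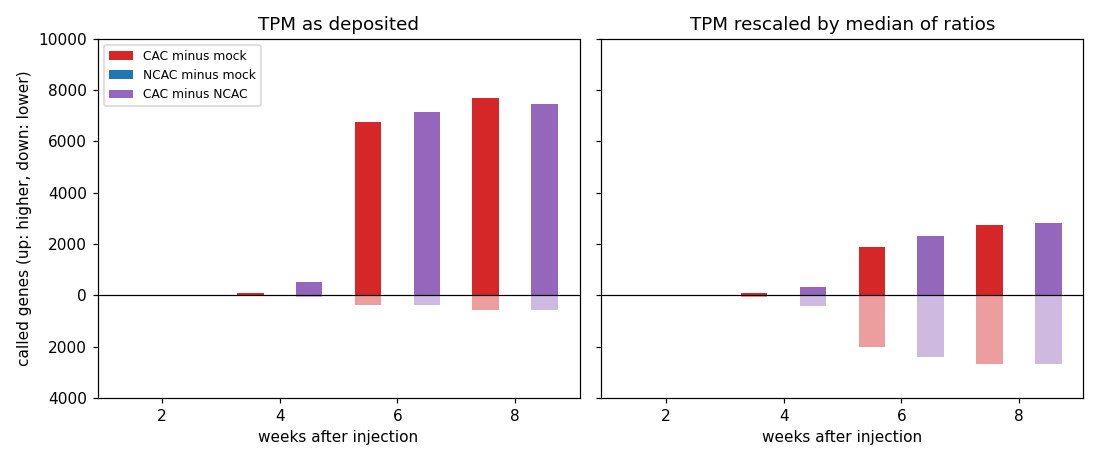
Number of genes called higher and lower by limma in each comparison and week, as deposited and after median-of-ratios rescaling. For CAC minus mock at 8 weeks the bars stand at 7707 higher and 565 lower as deposited and at 2761 and 2690 after rescaling.

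**Figure D3:**
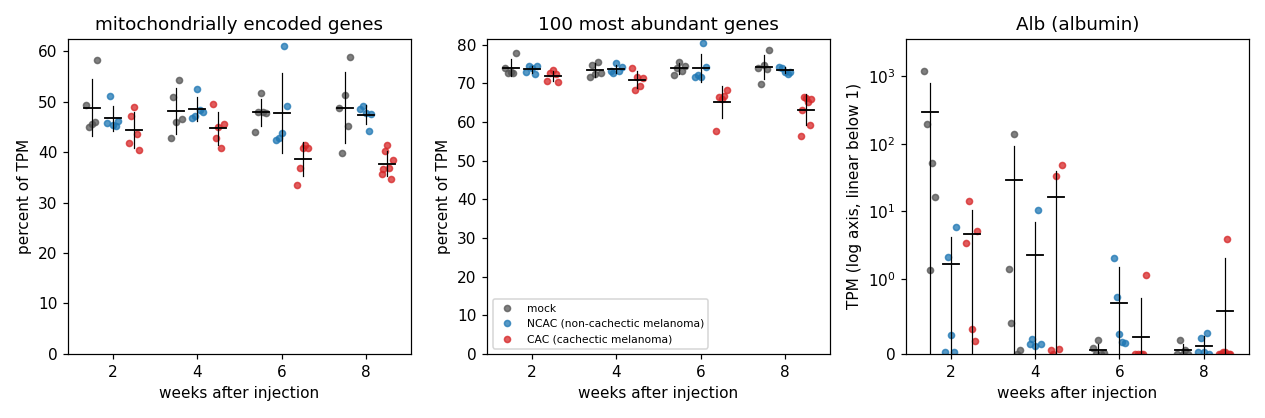
Percent of TPM in mitochondrially encoded genes, percent in the 100 most abundant genes and TPM of albumin (Alb, on a log axis that is linear near 0), with each point a library of mock, NCAC or CAC muscle by week. The 100 most abundant genes hold a mean of 63.2% of TPM in CAC and 74.2% in mock libraries at 8 weeks, and albumin reaches 1196 TPM in mock replicate 1 of 2 weeks.

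Gene lists at 6 weeks stood against a background of 6741 genes called higher among all 11107, and none passed camera as deposited. In the interleukin-6 and acute-phase list 22 of 25 genes rose (22 adjusted over the list alone, 18 after rescaling), with Osmr at a log2 change of 1.91, Stat3 at 1.95 and Il1r1, an interleukin-1 receptor, at 1.51 (adjusted p = 0.246 with an estimated correlation, and 0.0485 after rescaling, where the list passed). All 58 ribosomal protein genes rose (58 adjusted over the list alone, 52 after rescaling, adjusted p = 0.366 with an estimated correlation). Of 23 glucocorticoid-responsive genes 19 rose (19 adjusted over the list alone, 13 higher and 1 lower after rescaling, adjusted p = 0.814). Of 31 proteasome genes 31 rose, 15 of them after rescaling (31 adjusted over the list alone, adjusted p = 0.705 with an estimated correlation). Of nuclear-encoded oxidative phosphorylation genes 1 rose and 23 fell (1 and 20 adjusted over the list alone, none and 50 after rescaling), with Ndufs1, a core subunit of complex I, at -0.57. The list stood at an adjusted p = 0.0909 with an estimated correlation. In the tricarboxylic acid cycle 11 of 21 genes fell (10 adjusted over the list alone, 20 after rescaling, adjusted p = 0.077), with Mdh2, mitochondrial malate dehydrogenase, at -0.55 and at -0.99 rescaled. The ubiquitin ligase gene Trim63 was at 803 ± 714 against 152 ± 39.8 TPM (SD, n = 5) and rose (log2 change 1.93, adjusted p = 0.00272, 5 of 5). Fbxo32, its partner in atrophy, was called at 1.56 (adjusted p = 0.0145, 4 of 5), but not after rescaling (1.13, adjusted p = 0.094) or without CAC replicate 1 (1.17, adjusted p = 0.084).

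At 8 weeks the metallothioneins and acute-phase genes were higher in CAC muscle. Mt2 averaged 2293 ± 1368 TPM in CAC muscle (SD, n = 7) against 6.70 ± 3.57 TPM in mock muscle (n = 5), a 342-fold difference, and its neighbour Mt1 was 114-fold higher. Serpina3n, a secreted protease inhibitor, averaged 214 ± 221 (137 without CAC replicate 6) against 2.17 ± 0.846 TPM, and Lcn2, an iron-binding acute-phase protein, was 251-fold higher. Socs3 averaged 58.7 ± 18.0 against 2.13 ± 0.595 TPM, and the stress-induced mTORC1 inhibitor Ddit4 was 35.1-fold and the transcription factor Cebpd 33.7-fold higher (22.6- and 21.9-fold without CAC replicate 1). By limma the log2 change was 7.59 for Mt2 (SE 0.83, adjusted p = 8.09e-11), 6.15 for Mt1 (adjusted p = 2.44e-11), 5.41 for Serpina3n (SE 0.52, adjusted p = 2.7e-12), 5.02 for Lcn2 (adjusted p = 2.78e-10), 4.31 for Ddit4 (adjusted p = 7.76e-08), 4.30 for Cebpd (adjusted p = 2.57e-09) and 4.21 for Socs3 (SE 0.24, adjusted p = 5.71e-20), each higher in 7 of 7 libraries. In the interleukin-6 and acute-phase list 23 of 25 genes rose (23 adjusted over the list alone, 22 after rescaling), with a median log2 change of 2.12 as deposited and 1.69 rescaled. In the glucocorticoid-responsive list 21 of 23 rose (21 adjusted over the list alone, 18 higher and 1 lower after rescaling), Fkbp5 among them at 3.27 and the sulfotransferase Sult1a1 at 2.14. Neither list passed camera (adjusted p = 0.291 and 0.642 with an estimated correlation). In GRCm38 coordinates of GENCODE M21, Mt2 lies on chromosome 8 at 94172664 to 94173568 and Mt1 beside it at 94179082 to 94180327, both on the plus strand. Socs3 lies on chromosome 11 at 117966079 to 117970047 on the minus strand. CAC replicate 3 stood apart from its group with 32.3 TPM of Mt2. It also held 3252 TPM of the haemoglobin gene Hba-a1, against at most 462 TPM in the other CAC libraries of that week.

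The atrophy ligases Trim63 and Fbxo32 rose with a wide spread at 8 weeks. Trim63 (chromosome 4, 134315120 to 134329629, plus strand) averaged 1367 ± 1752 TPM in CAC (SD, n = 7) against 119.9 ± 27.0 TPM in mock muscle (n = 5), and Fbxo32 (chromosome 15, 58175879 to 58214932, minus strand) 463 ± 524 against 73.9 ± 16.3 TPM. Without CAC replicate 1 the CAC means were 818 and 301 TPM. Both were higher than the mock mean in 6 of 7 libraries, with a log2 change of 2.34 (SE 0.52, adjusted p = 8.44e-05) and 1.65 (SE 0.52, adjusted p = 0.00428). These SEs come from a spread pooled over all groups, while CAC libraries varied far more than mock libraries, so they understate the uncertainty of both genes. Among ubiquitin ligases and proteolysis regulators 23 of 26 genes rose (23 adjusted over the list alone), Fbxo31 at 1.84 and the protease gene Capn2 at 1.01 (0.51 rescaled), and 10 were higher and 3 lower after rescaling. All 31 proteasome genes rose (31 adjusted over the list alone), with Psma3 at 0.87 (0.35 rescaled) and Psmd4 at 1.18 (0.66 rescaled), while after rescaling 7 were higher and 2 lower. Of 31 autophagy and lysosome genes 28 rose (28 adjusted over the list alone) and 17 were higher and 3 lower after rescaling, led by Lamp2 (1.28) and by Map1lc3a (1.49), a protein of the autophagosome membrane. None of the 3 lists passed camera (adjusted p = 0.846, 0.846 and 0.841 with an estimated correlation). Without the 3 libraries farthest out on the first principal component, a choice made after seeing the data, the log2 change was 1.3 for Trim63 (adjusted p = 0.0031) and 0.74 for Fbxo32 (adjusted p = 0.13). Rescaled, Fbxo32 stood at 1.14 (adjusted p = 0.0536).

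Of the genes of mitochondrial energy metabolism more fell than rose at 8 weeks. Ndufs1 averaged 136 ± 28.5 TPM in CAC at 8 weeks (SD, n = 7) against 239 ± 11.3 TPM in mock muscle (n = 5), and Mdh1, the cytosolic malate dehydrogenase, 316 ± 70.7 against 577 ± 69.4 TPM. Of 52 nuclear-encoded oxidative phosphorylation genes 31 fell and 4 rose (30 and 4 adjusted over the list alone). Of 13 mitochondrially encoded genes 11 fell (11 adjusted over the list alone). Of 21 tricarboxylic acid cycle genes 17 fell and 1 rose (17 and 1 adjusted over the list alone). After rescaling 50, 13 and 20 were lower and none higher. By camera all 3 lists passed (adjusted p = 0.0448, 0.0413 and 0.0357). The log2 change was -0.83 for Ndufs1 (SE 0.11, adjusted p = 7.17e-09, -1.35 rescaled), -0.85 for Cox7a1 (adjusted p = 9.46e-08, -1.37 rescaled), -0.49 for mt-Co1 (adjusted p = 2.47e-06, -1.01 rescaled), -0.89 for Mdh1 (adjusted p = 3.53e-07, -1.41 rescaled) and -0.82 for Dlat, a subunit of pyruvate dehydrogenase (adjusted p = 6.32e-07, -1.33 rescaled), each lower in 7 of 7 libraries. Myokines and other muscle-secreted factors were the fourth list to pass (adjusted p = 0.0413, direction down), with 5 higher and 5 lower of 15 genes (5 and 5 adjusted over the list alone, 2 and 7 after rescaling). The median of this list was 0.05, where that of all genes was 0.46. Camera tests a list against the other genes, so its direction is relative to them. Among the myokines Ostn fell by 2.25, Fndc5, the precursor of irisin, fell by 0.85 and Il15 fell by 0.87. No list passed after rescaling, without the filter, in a fit of these weeks alone, without the mitochondrially encoded genes or without CAC replicate 3. Only 1 list, the tricarboxylic acid cycle, passed without mock replicate 5 or with the replicate number as a block. The oxidative phosphorylation list also lost its call without CAC replicates 1 or 7 (adjusted p = 0.051 and 0.0568), without mock replicates 1, 3 or 4 (adjusted p = 0.0525, 0.0524 and 0.0525) and without the 3 libraries farthest out on the first principal component (adjusted p = 0.0721).

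**Figure D4:**
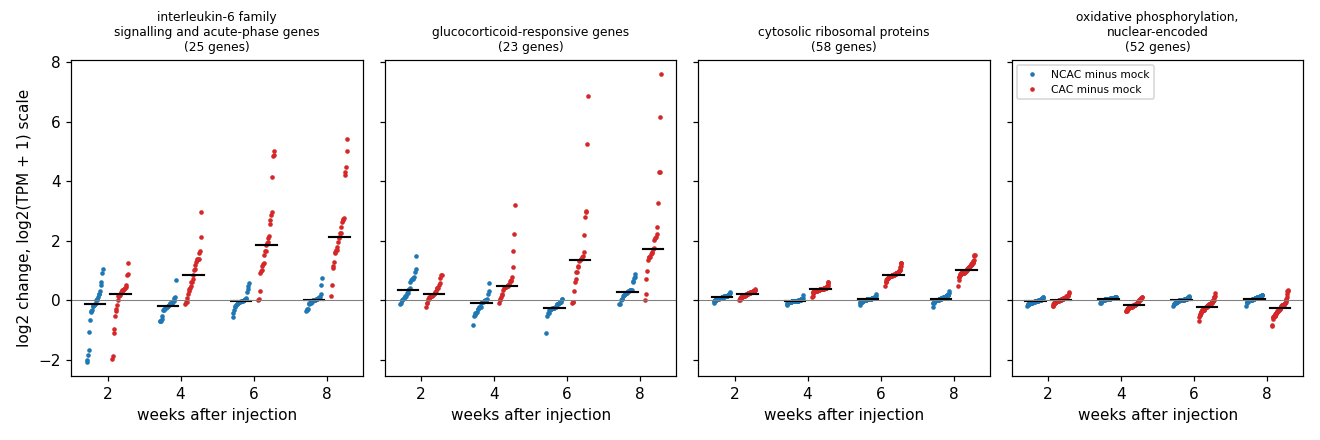
Log2 change of each gene of 4 lists by week, NCAC minus mock and CAC minus mock, with each point a gene and the black bar the median, as deposited. For CAC minus mock at 8 weeks the medians are 2.12 in the interleukin-6 and acute-phase list, 1.73 in the glucocorticoid list, 1.00 in the ribosomal protein list and -0.28 in the oxidative phosphorylation list, and none of these medians changes sign after rescaling (1.69, 1.22, 0.48 and -0.80).

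Genes of the contractile apparatus moved in both directions. Actc1 averaged 8.32 ± 6.67 TPM in CAC muscle at 8 weeks (SD, n = 7) against 134 ± 145 TPM (n = 5, 70.2 TPM without mock replicate 3). Mb, the oxygen-binding myoglobin, averaged 3021 ± 1047 against 7663 ± 994 TPM, and Casq1, the calcium buffer of the sarcoplasmic reticulum, was 0.474 times the mock mean. Sln, an inhibitor of the calcium pump, was 12.6-fold higher and the intermediate filament gene Des 2.69-fold. With limma the log2 change was -3.65 for Actc1 (SE 0.52, adjusted p = 4.92e-08, lower in 7 of 7), -1.42 for Mb (adjusted p = 8.47e-08, 7 of 7), -1.68 for Casq1 (adjusted p = 0.000367, 6 of 7), 3.07 for Sln (adjusted p = 1.12e-08, higher in 7 of 7) and 1.42 for Des (adjusted p = 4.16e-09, 7 of 7). Of 20 fast-fibre genes 6 rose and 6 fell (6 and 6 adjusted over the list alone, adjusted p = 0.437 with an estimated correlation). In this list none was higher and 11 were lower after rescaling, where Tnni2 turned from 0.36 to -0.16. Of 18 slow-fibre genes 5 rose and 3 fell (5 and 3 adjusted over the list alone, 3 and 4 after rescaling, adjusted p = 0.371). Among 14 developmental and regeneration genes 4 rose and 1 fell (3 and 1 adjusted over the list alone), which turned to 1 and 4 after rescaling (adjusted p = 0.291 with an estimated correlation). Of 21 genes of denervation and the neuromuscular junction 7 rose and 1 fell (6 and 1 adjusted over the list alone), which turned to 2 higher and 9 lower after rescaling (adjusted p = 0.371). Its member Cdkn1a, a cell cycle inhibitor, rose in 6 of 7 libraries (2.23, adjusted p = 5.53e-05). Myh4, the fast IIb myosin, was not called (0.34, adjusted p = 0.25). The IIa myosin Myh2 was called at -1.32 (adjusted p = 0.0156), but not without CAC replicate 1 (-0.75, adjusted p = 0.1) or mock replicate 2 (-1.12, adjusted p = 0.0536). Mstn, the inhibitor of muscle growth, was called at 1.04 (adjusted p = 0.002) but not after rescaling (0.54, adjusted p = 0.1).

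Genes of translation, stress responses and metabolism were counted against the same background of 7707 genes called higher among 11107, and none of these lists passed camera. All 58 ribosomal protein genes rose (58 adjusted over the list alone, 55 after rescaling, adjusted p = 0.371 with an estimated correlation), Rpl3 by 1.51 on the log2 scale (1.00 rescaled) and Rps23 by 1.06 (0.54 rescaled). Of 22 growth factor and translation control genes 16 rose (18 adjusted over the list alone, 10 higher and 3 lower after rescaling, adjusted p = 0.846), among them Myc at 2.35. Eif4ebp1, which blocks cap-dependent translation, rose by 3.13 and the amino acid transporter subunit Slc3a2 by 1.71. In their list of integrated stress and unfolded-protein responses 17 of 24 rose and 1 fell (17 and 1 adjusted over the list alone, 7 and 3 after rescaling, adjusted p = 0.892 with an estimated correlation). Of 20 chaperone genes 14 rose (14 adjusted over the list alone), but 2 were higher and 4 lower after rescaling (adjusted p = 0.892), where Hspe1 turned from 0.49 to -0.03. Of 22 antioxidant genes 19 rose and 2 fell (19 and 2 adjusted over the list alone, 11 and 3 after rescaling, adjusted p = 0.846), with the plasma glutathione peroxidase Gpx3 at 1.96. In glycolysis and glycogen metabolism 9 of 25 rose and 3 fell (8 and 3 adjusted over the list alone), which turned to 5 higher and 14 lower after rescaling (adjusted p = 0.468 with an estimated correlation). Of 31 genes of fatty acid use 10 rose and 9 fell (10 and 9 adjusted over the list alone, 5 and 12 after rescaling, adjusted p = 0.371), Ucp2 at 1.39 and Fabp3 at -1.33. Of 17 lipid synthesis genes 11 rose and 1 fell (11 and 1 adjusted over the list alone, 5 and 2 after rescaling, adjusted p = 0.892). Pdk4, which blocks pyruvate oxidation, was called at 1.29 (adjusted p = 0.03), but not without CAC replicate 1 (0.86, adjusted p = 0.13), 2 (adjusted p = 0.058) or 6 (adjusted p = 0.099), mock replicate 3 (adjusted p = 0.053) or 5 (adjusted p = 0.06), or after rescaling (0.77, adjusted p = 0.23).

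Markers of immune and stromal cells were counted against the 7707 of 11107 genes called higher at 8 weeks. Of 14 macrophage markers 13 rose (13 adjusted over the list alone, 7 after rescaling), with the scavenger receptor gene Cd163 6.09-fold higher. Of 3 neutrophil markers 3 rose (3 adjusted over the list alone, 2 after rescaling), with S100a8 5.97-fold higher (3.79-fold without CAC replicate 4). Of 14 endothelial genes 12 rose and 1 fell (12 and 1 adjusted over the list alone, 7 and 2 after rescaling). Of 12 smooth muscle and pericyte genes 10 rose (10 adjusted over the list alone, 6 higher and 1 lower after rescaling). Of 12 markers of fibro-adipogenic progenitors 6 rose (6 adjusted over the list alone, 3 and 2 after rescaling). Of 9 satellite cell genes 4 rose (4 adjusted over the list alone, 2 and 2 after rescaling). Of 10 Schwann cell genes 6 rose (5 adjusted over the list alone, 1 after rescaling). Of 12 adipocyte genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, 3 and 1 after rescaling). In that order the adjusted p with an estimated correlation was 0.846, 0.638, 0.841, 0.846, 0.892, 0.846, 0.846 and 0.846. None of 6 erythroid genes was called by limma, while 8454 of all genes were at an unadjusted p under 0.05 in this contrast (adjusted p = 0.456 with an estimated correlation). Both melanocyte genes tested, Mitf and Sox10, rose as deposited (2 adjusted over the list alone) and neither was called after rescaling, nor was Sox10 without mock replicate 5 (0.25, adjusted p = 0.108). The single keratinocyte gene tested was not called. Of 16 NF-kB and chemokine genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, 7 and 2 after rescaling, adjusted p = 0.846 with an estimated correlation), with the tumour necrosis factor receptor gene Tnfrsf1a at 1.65. Of 24 interferon response genes 4 rose and 4 fell (2 and none adjusted over the list alone), which turned to none higher and 13 lower after rescaling (adjusted p = 0.456). The mean log2(TPM + 1) of this list was 2.79 ± 0.191 in CAC and 2.82 ± 0.541 in mock muscle (SD, n = 7 and 5). Mock replicates 1 and 2 were high (3.30 and 3.505) and raised the mock level used here. Mock muscle averaged 2.49, 2.38 and 2.51 at 2, 4 and 6 weeks. Of 23 TGF-beta, activin and BMP genes 13 rose and 3 fell (13 and 3 adjusted over the list alone), which turned to 6 and 7 after rescaling (adjusted p = 0.846 with an estimated correlation), Nog, a BMP antagonist, at 2.01. Of 33 extracellular matrix genes 8 rose and 4 fell (7 and 3 adjusted over the list alone), which turned to 3 higher and 12 lower after rescaling (adjusted p = 0.487), with the collagen cross-linking enzyme Lox at 1.94 and Col6a2 at -0.93.

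The next question was whether the change grew between weeks. All 6 genes called at 2 weeks were also called higher at 4, 6 and 8 weeks, Socs3 and Stat3 among them, where 0.0535, 3.64 and 4.16 would be expected of independent lists. Of the 99 genes higher at 4 weeks 97 were higher at 6 weeks and 97 at 8 weeks (60.1 and 68.7 expected). In all, 6444 genes were higher and 291 lower at both 6 and 8 weeks (4677 and 18.4 expected), with 1 in opposite directions. After rescaling 1523 were higher and 1716 lower at both weeks (465.3 and 487.8 expected). A direct test of the difference between the effects at 8 and 2 weeks called 4044 genes higher and 286 lower (1011 and 1193 after rescaling, with a median of all genes of 0.33). Mt2 led it with a log2 difference of 6.84 (SE 1.22, adjusted p = 6.55e-05), Serpina3n followed at 5.29 (adjusted p = 3.46e-06), and Myh2 stood at -2.36 (adjusted p = 0.0118). In this test 25 of 25 interleukin-6 and acute-phase genes were higher (25 adjusted over the list alone, 22 after rescaling, adjusted p = 0.0807 with an estimated correlation). Of 21 tricarboxylic acid cycle genes 15 were lower (17 adjusted over the list alone, 20 after rescaling, adjusted p = 0.0638). The interleukin-6 list passed after rescaling (adjusted p = 0.0265) and without the filter (adjusted p = 0.0476). The tricarboxylic acid cycle list passed without the filter (adjusted p = 0.0476) and without CAC replicate 5 of 2 weeks (adjusted p = 0.0362) or of 8 weeks (adjusted p = 0.0466). The liver gene Alb at 4.19 (adjusted p = 0.0198) rests on mock libraries of 2 weeks that hold liver transcripts, and was not called without mock replicate 1 of 2 weeks (3.08, adjusted p = 0.066). Without the 3 libraries with over 100 TPM of albumin 2845 genes were called, and without the 3 libraries farthest out on the first principal component 2775, both chosen after seeing the data.

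CAC and NCAC mice both carried melanoma cells, so their difference asks what is particular to the cells called cachectic. At 2 weeks 7 genes were higher in CAC muscle, with Trim72 at 203 ± 34.2 against 96.8 ± 3.65 TPM (SD, n = 5 in each group), Jak3 at 7.91 ± 1.67 against 3.27 ± 0.576 TPM and Stat3 at 20.6 ± 4.65 against 10.6 ± 1.06 TPM. By limma the log2 change was 1.05 for Trim72 (adjusted p = 8.72e-06), 1.05 for Jak3 (adjusted p = 0.000272), 0.87 for Stat3 (adjusted p = 0.0129) and 0.90 for Abtb2 (adjusted p = 0.0129), each higher in 5 of 5. Socs3 was not called (1.04, adjusted p = 0.164), except without CAC replicate 1 (1.36, adjusted p = 0.0023). The count was 11 without CAC replicate 1, 3 without CAC replicate 3, 2 without CAC replicate 4 or 5, 3 without NCAC replicate 1 and 2 without NCAC replicate 2. Stat3 was lost without CAC replicates 3, 4 or 5 or NCAC replicate 2 (adjusted p = 0.11, 0.099, 0.11 and 0.085), and Abtb2 was lost without CAC replicates 4 or 5 or NCAC replicates 1 or 2 (adjusted p = 0.099, 0.11, 0.088 and 0.06). After rescaling 5 were higher and 1 lower.

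At 4 weeks the comparison of CAC with NCAC muscle called 520 genes higher and 65 lower. Socs3 was 10.8-fold higher (log2 change 2.86, adjusted p = 1.99e-11), Stat3 2.9-fold (1.45, adjusted p = 3.94e-08) and Apod 4.45-fold (1.92, adjusted p = 1.79e-05). Actc1 was at 42.3 ± 23.3 against 228 ± 49.1 TPM (-2.73, adjusted p = 0.00177). Cyfip2, a regulator of actin, was at 1.79 ± 1.62 against 12.5 ± 5.71 TPM (-2.35, adjusted p = 0.00108) and Fabp3 at 735 ± 146 against 1478 ± 164 TPM (-1.02, adjusted p = 0.00488). Each of these 6 genes lay on 1 side of the NCAC mean in 5 of 5 libraries. The mitochondrial trifunctional protein gene Hadha, which oxidises fatty acids, fell by 0.58 (adjusted p = 0.00163) and the tricarboxylic acid cycle gene Dlst fell by 0.44 (adjusted p = 0.00353). Of 21 tricarboxylic acid cycle genes 5 fell (15 adjusted over the list alone, 19 after rescaling) and the list passed camera (adjusted p = 0.0384), as did the myokine list with 3 lower (3 adjusted over the list alone, 4 after rescaling, adjusted p = 0.0406). Both calls ended after rescaling (adjusted p = 0.162 and 0.215), in a fit of this week alone (adjusted p = 0.205 and 0.188) and without the mitochondrially encoded genes (adjusted p = 0.0584 for both). The replicate number as a block ended both as well. That of myokines also ended with a pseudocount of 0.1 (adjusted p = 0.0567) and without the filter (adjusted p = 0.133). After rescaling the interleukin-6 and acute-phase list passed instead (adjusted p = 0.0369), and 311 genes were higher and 406 lower. The count was 130 without CAC replicate 2, 172 without CAC replicate 4, 1494 without CAC replicate 1, and 340, 294 and 292 without NCAC replicates 2, 3 and 5. The number of lists passing was 1 without CAC replicates 1 or 3 or NCAC replicate 2 and 0 without NCAC replicate 3.

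At 6 and 8 weeks CAC muscle differed from NCAC muscle as widely as from mock muscle. Mt2 averaged 9.93 ± 4.91 TPM in NCAC muscle at 6 weeks and 13.3 ± 18.2 TPM at 8 weeks (SD, n = 5), 161- and 173-fold below CAC muscle (445-fold at 8 weeks without NCAC replicate 3). Serpina3n averaged 2.32 ± 0.696 and 1.88 ± 0.44 TPM, 57.2- and 114-fold below (30.8-fold without CAC replicate 1 of 6 weeks and 72.8-fold without CAC replicate 6 of 8 weeks). At 8 weeks Socs3 was 37.3-fold higher (log2 change 4.50, adjusted p = 2.44e-21, 7 of 7 libraries). Fst, the follistatin gene, was called at 0.62 (adjusted p = 0.00258, 7 of 7) but not after rescaling (0.30, adjusted p = 0.11). Trim63 was 7.23-fold higher at 6 weeks (2.38, adjusted p = 0.000266, 5 of 5) and 9.52-fold at 8 weeks (2.07, adjusted p = 0.000422, 6 of 7), or 5.70-fold without CAC replicate 1 of 8 weeks. Fbxo32 was called at 8 weeks at 1.57 (adjusted p = 0.00677, 5 of 7) but not after rescaling (1.08, adjusted p = 0.066). Actc1 fell by 3.38 at 6 weeks (adjusted p = 2.19e-06) and fell by 3.52 at 8 weeks (adjusted p = 1.06e-07). Ighm, the immunoglobulin mu chain of B cells, fell by 2.48 (adjusted p = 0.000373) and fell by 3.54 (adjusted p = 3.48e-07). Both were lower in every CAC library. By limma 7131 genes were higher and 391 lower at 6 weeks and 7446 and 560 at 8 weeks, with medians of all genes of 0.42 and 0.43. After rescaling there were 2315 and 2413, and 2805 and 2697. At 8 weeks camera passed oxidative phosphorylation (35 lower and 2 higher of 52, 35 and 2 adjusted over the list alone, adjusted p = 0.0341) and mitochondrially encoded genes (12 lower of 13, 12 adjusted over the list alone, adjusted p = 0.0341). It also passed the tricarboxylic acid cycle (19 lower of 21, 19 adjusted over the list alone, adjusted p = 0.0199) and myokines (4 higher and 5 lower of 15, 4 and 5 adjusted over the list alone, adjusted p = 0.0341, direction down, with a median of 0.03 where that of all genes was 0.43). After rescaling none of these passed, while 51, 13, 20 and 7 of their genes were lower. No list passed without the filter, in a fit of this week alone or without the mitochondrially encoded genes. In total 1 list passed without CAC replicate 3 or with the replicate number as a block, and 2 without NCAC replicate 3. The mitochondrially encoded list also lost its call without CAC replicate 5 (adjusted p = 0.0567). At 6 weeks no list passed.

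NCAC muscle was close to mock muscle. At 2 weeks 18 genes were lower and none higher, all of them with their highest value in mock replicate 1. The largest changes were liver transcripts such as Alb (1.67 ± 2.55 against 292 ± 511 TPM, SD, n = 5 in each group, with a mock mean of 65.7 TPM without mock replicate 1 and an NCAC mean of 0.598 TPM without NCAC replicate 5), Apoa2 and Ahsg. With limma the log2 change was -4.82 for Alb (SE 1.05, adjusted p = 0.0261), -3.98 for Apoa2 (adjusted p = 0.0227) and -3.35 for Ahsg (adjusted p = 0.0227), each lower in 5 of 5. None of the 18 genes was called without mock replicate 1 or 2 or NCAC replicates 1, 3 or 4, 3 were without NCAC replicate 2, and 39 and 28 were called without mock replicates 3 and 5. At 4 and 6 weeks limma called 0 genes, with 143 and 118 at an unadjusted p under 0.05. These are 1.29% and 1.06% of the genes tested, below the 1 in 20 that chance gives. The test may therefore have been too strict here and may have missed small changes. Socs3 stood at 1.91 ± 0.515 against 1.69 ± 0.27 TPM and at 1.72 ± 0.817 against 1.54 ± 0.42 TPM. At 8 weeks 1 gene, the histone gene Hist2h2aa2, was called (1.96, adjusted p = 0.0294, 5 of 5), a gene with a near-identical copy whose value is uncertain. It averaged 15.5 ± 3.23 against 4.37 ± 3.47 TPM, but mock muscle held 15.0 TPM of Hist2h2aa2 at 2 weeks, 16.7 at 4 and 18.6 at 6 weeks and was itself lower at 8 than at 2 weeks (-1.87, adjusted p = 0.00681), so a change in NCAC muscle is not shown. The call ended with a pseudocount of 0.1, in a fit of this week alone, without CAC libraries in the fit, and without NCAC replicates 1, 2 or 3 or mock replicates 2 or 4 (adjusted p = 0.083, 0.23, 0.12, 0.47 and 0.1). In the same comparison 4 genes were called without NCAC replicate 5 and 2 without mock replicate 3. None of 24 interferon response genes was called over all genes (166 of all genes at an unadjusted p under 0.05), and 15 were lower when adjusted over the list alone. The list passed camera (median log2 change -0.50, adjusted p = 0.00519) but not without mock replicate 1, without the filter (adjusted p = 0.0699) or in a fit of this week alone (adjusted p = 0.0762). By contrast the macrophage list passed beside it without NCAC replicate 4 (adjusted p = 0.0258) or mock replicate 4 (adjusted p = 0.0445). The overlap of calls with CAC minus mock at 8 weeks was 1 gene, Hist2h2aa2, where independent lists gave 0.694. Simulated data gave a mean of 0.02, but CAC was left unchanged there as well as NCAC, so this is no reference for the real overlap. With the mock libraries split between the comparisons the overlap was 0 to 2. The covariance of the log2 changes was 0.0143, against 0.0142 simulated, and their correlation 0.184, against 0.467 simulated. The simulated correlation is no reference either, since it rests on an unchanged CAC group.

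The test of whether the NCAC effect differed between 8 and 2 weeks called 0 genes by limma (221 at an unadjusted p under 0.05), and 1 list passed camera, macrophage markers, with 6 genes lower adjusted over the list alone and none over all genes (adjusted p = 0.0399). The call ended after rescaling (adjusted p = 0.0849), without the filter (adjusted p = 0.198), in a fit of these weeks alone (adjusted p = 0.117) and without the libraries with over 100 TPM of albumin (adjusted p = 0.0717). With the replicate number as a block the call ended as well. It also ended without NCAC replicates 3 or 5 of 2 weeks, mock replicates 2, 3 or 4 of 2 weeks, NCAC replicates 1 or 3 of 8 weeks, or mock replicates 1, 2 or 5 of 8 weeks (0 lists). In total 2 lists passed without NCAC replicate 2 of 2 weeks or mock replicates 3 or 4 of 8 weeks. Mock muscle itself differed between 8 and 2 weeks in 30 genes, 2 higher and 28 lower at 8 weeks, with Alb at -5.71 (adjusted p = 0.00571), Apoa2 at -4.78 (adjusted p = 0.00218) and Ahsg, the plasma protein fetuin-A, at -3.63 (adjusted p = 0.00571), each lower in 5 of 5. Without mock replicate 1 of 2 weeks 0 genes were called, and 5 without mock replicate 2, with Ahsg not among them (-3.30, adjusted p = 0.0523). No list passed in mock muscle between these weeks in the main fit, while 1 list did, higher at 8 weeks, without CAC libraries in the fit.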

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

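Tests chosen only after the result was seen were those of the mitochondrially encoded genes, the depth, the share of liver transcripts in the highest library, the single mock library behind the interferon genes, the macrophage score in fits of fewer libraries, and all tests on other splits of the libraries. Single libraries far from the others of their group were found by the gap to the nearest library over the range of the group. Applied to 16 measures in 12 groups, 192 tests in all, this found a library far from the others in 19 tests, some libraries more than once, where chance gives about 1 in 20 and so 9.6. In TPM, Mt2 stood at 32.3 in CAC replicate 3 of 8 weeks (next lowest 1925) and at 45.7 in NCAC replicate 3 of 8 weeks (next highest 6.06). CAC replicate 3 of 8 weeks was also low in Fkbp5, at 8.46 (next 76.95), while CAC replicate 1 of 6 weeks was high, at 185 (next 78.9). Cdkn1a was high in NCAC replicate 5 of 6 weeks (12.3, next 8.39), mock replicate 1 of 6 weeks (30.5, next 9.46) and NCAC replicate 3 of 8 weeks (60, next 10.6). Myh2 was low in mock replicate 5 of 2 weeks (186, next 435). Ppargc1a was high in CAC replicate 2 of 4 weeks (18.95, next 13.6) and low in NCAC replicate 4 of 6 weeks (7.78, next 12.4), and Fst was high in mock replicate 1 of 6 weeks (2.41, next 1.34). Albumin was high in NCAC replicate 4 of 4 weeks (10.54), mock replicate 3 of 4 weeks (142), CAC replicate 5 of 6 weeks (1.16) and CAC replicate 5 of 8 weeks (3.96). The share of mitochondrially encoded genes was high in NCAC replicate 2 of 2 weeks (51.1%) and NCAC replicate 3 of 4 weeks (52.6%). The rule did not flag the highest share of all, 61.1% in NCAC replicate 4 of 6 weeks, the library with the lowest size factor (0.613). Without that library CAC minus NCAC at 6 weeks called 6200 genes. Estimated reads were highest in mock replicate 5 of 6 weeks (55 times 1000000), and the interferon score, a measure added after the interferon pattern was seen, was low in NCAC replicate 2 of 2 weeks (1.85, next 2.61).

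Differences between groups were found by direct tests. The effects of CAC cells at 8 and 2 weeks differed in 4330 genes, and CAC from NCAC in 7, 585, 7522 and 8006 genes at 2, 4, 6 and 8 weeks. For each comparison 100 splits of the same libraries into groups of the same sizes were fitted, the real one included. Only the real split called as many genes for CAC minus mock at 6 weeks (real 7103, highest other 5421) and 8 weeks (real 8272, highest other 7645). This argues against chance there but does not exclude it, since 1 in 100 was not corrected for the 15 contrasts. At 4 weeks 2 splits called as many, the real one included (real 104, highest other 151), and at 2 weeks 4 did (real 6, highest other 26). Because other splits reached the real counts and the comparisons were not corrected for their number, these splits did not exclude chance for CAC minus mock at 2 or 4 weeks. The split with 26 genes at 2 weeks called several times the real count, and that with 151 at 4 weeks also exceeded it. The mock libraries of 2 weeks that hold liver transcripts are among those split, but which libraries decided was not tested. For CAC minus NCAC only the real split called as many genes at 2 weeks (1 split, real 7, highest other 1), 4 weeks (1 split, real 585, highest other 451), 6 weeks (1 split, real 7522, highest other 6500) and 8 weeks (1 split, real 8006, highest other 6805). This argues against chance in CAC minus NCAC, with the same limit that the number of contrasts was not corrected for. For the difference of the CAC effects 2 splits called as many, the real one included (real 4330, highest other 4722). Libraries were exchanged within each week, which removes the effect at 8 weeks itself, so these splits do not test whether the effects differ. For NCAC minus mock at 2 weeks (3 splits, real 18, highest other 26) and mock muscle between weeks (1 split, real 30, highest other 29), whose calls end without mock replicate 1 of 2 weeks, the splits record where that library falls and say nothing of a difference between groups. Chance could not be excluded for NCAC minus mock at 8 weeks (9 splits, real 1, highest other 2). A real count of 0 is reached by every split by construction, so the 100 splits say nothing of NCAC minus mock at 4 weeks (0 genes by limma, 143 at an unadjusted p under 0.05, highest other 15), 6 weeks (0 genes with 118, highest other 1) or the difference of the NCAC effects (0 genes with 221, highest other 1). The libraries behind the split with 15 genes at 4 weeks were not traced, and mock replicate 3 of that week holds over 100 TPM of albumin.

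The first pattern weighed was that over 93% of the genes called in CAC muscle at 6 and 8 weeks were higher. A lower share of mitochondrially encoded RNA alone would leave an even split without these genes, but 79.2% were still higher at 8 weeks (76.9 to 80.9 with each library left out), and a difference in depth was excluded by a ratio of estimated reads of 1.01. Leaving out the 100 most abundant genes and restoring the total gave 53.2% higher at 8 weeks (51.2 to 56.0) and 56.2% at 6 weeks, and leaving out 20 or 500, sets added later, gave 73.2% and 50.3%. A candidate explanation is therefore that lower shares of abundant muscle transcripts raised the TPM of all others. Whether the muscle held more of the other transcripts or less of the abundant ones cannot be read from TPM.

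The second pattern was the lower liver genes of NCAC against mock muscle at 2 weeks. Of 30 liver markers, 30 were highest in mock replicate 1, which held 82.2% of the group's summed liver-marker TPM, against a change shared evenly by the mock libraries. The sums were 3923, 565, 13.1, 194 and 77.01 TPM in mock replicates 1 to 5 and at most 30.6 TPM in NCAC libraries of that week, so a smaller rise in several mock libraries was left open. The log2 ratios of 29 markers between the libraries with the most albumin had an interquartile range of 0.34 about a median of 2.74, as RNA of 1 tissue in unequal amounts would give. Liver RNA in single mock libraries may therefore explain the calls. Mixing during dissection and mixing during library preparation were not tested apart.

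The last pattern was the lower interferon genes of NCAC against mock muscle at 8 weeks, 24 of 24 list members. With the macrophage score in the model the median was -0.48 (-0.50 without it), but -0.31 with no CAC libraries and -0.15 with the compared libraries alone, since the pooled slope on the score was 0.0977 against 0.836 in the compared libraries, so a lower share of macrophages (mean score 1.79 against 2.20 in mock muscle) cannot be told apart. Mock libraries of 8 weeks scored 0.36 above those of other weeks, but replicates 1 and 2 carried this (3.30 and 3.505, the others 2.38 to 2.49), the same libraries that held most of the sparse T-cell transcript Cd3d (0.23 and 0.459 TPM), and NCAC libraries of 8 weeks scored -0.24 against other weeks. Without each mock library in turn the weakest median was -0.31, and since a margin of 1 SD of these medians (0.121) was added after the value was seen, 1 mock library with high interferon genes cannot be told apart from a change of the group. Of all splits of the 10 libraries into equal groups, 10 gave as large a difference of mean scores (real -0.54, highest other 0.65, exact permutation p = 0.0794, smallest possible 0.00794), so chance could not be excluded.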

How the results depend on the processing

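Over all fits with a library left out, 11838 results of single genes, called or not, kept their direction and side of the threshold, 507 lost a call and 17 gained one. With rescaling 832 of 1000 such results, called or not, kept both, 158 lost a call, 1 gained one and 9 reversed. With a pseudocount of 0.1 987 kept both and 13 lost a call, and with no filter 966 and 34. In what follows counts are genes called, and the cause was not tested unless the setting itself removes libraries or genes. The reversed log2 changes, which follow from the shift of the median, were those of Rapsn in CAC minus mock at 6 weeks (-0.0769) and 8 weeks (-0.00195), Tnni2 in CAC minus mock at 6 weeks (-0.0558) and 8 weeks (-0.16) and in CAC minus NCAC at 6 weeks (-0.20) and 8 weeks (-0.19), Hspe1 in CAC minus mock at 8 weeks (-0.0259), and Hspa4 (-0.11) and Mitf (-0.00627) in CAC minus NCAC at 6 weeks. Rescaling gave CAC minus mock 12 genes at 2 weeks, 166 (1 list, interleukin-6) at 4, 3886 (1 list, the same) at 6 and 5451 (0 lists) at 8 weeks. It gave NCAC minus mock 2 genes at 8 weeks, CAC minus NCAC 1 list at 4 weeks (interleukin-6, higher, where the 2 as deposited were lower), 4728 genes at 6 weeks and 0 lists at 8 weeks, 2204 genes and 1 list for the difference of the CAC effects, 0 lists for that of the NCAC effects, 3239 genes shared by 6 and 8 weeks and 2 shared by CAC and NCAC. A pseudocount of 0.1 gave NCAC minus mock 6 genes and 1 list at 2 weeks and 0 genes at 8 weeks, CAC minus NCAC 1 list at 4 weeks, and 0 genes shared by CAC and NCAC. No filter gave CAC minus mock 12 genes at 2 weeks and 0 lists at 8 weeks, NCAC minus mock 117 genes at 2 weeks and 2 genes and 0 lists at 8 weeks, CAC minus NCAC 1 list at 4 weeks and 0 at 8 weeks, 3 lists for the difference of the CAC effects, 0 for that of the NCAC effects and 188 genes for mock 8 minus 2 weeks. Only the groups of the compared weeks gave CAC minus mock 3 genes at 2 weeks and 0 lists at 8 weeks, NCAC minus mock 0 genes at 2 weeks (281 at an unadjusted p under 0.05 by limma with all groups) and 0 genes and 0 lists at 8 weeks, CAC minus NCAC 1070 genes and 0 lists at 4 weeks and 0 lists at 8 weeks, 0 genes shared by CAC and NCAC, 0 lists for the difference of the NCAC effects and 4 genes for mock 8 minus 2 weeks. The replicate number as a block gave CAC minus mock 1 list (tricarboxylic acid cycle) at 8 weeks, CAC minus NCAC 4 genes at 2 weeks, 0 lists at 4 weeks and 1 list (the same) at 8 weeks, 0 lists for the difference of the NCAC effects and 18 genes for mock 8 minus 2 weeks. Same-number pairs exceeded a correlation of 0.1 in 15 of 60 pairs and throughout in 0 of 12 comparisons (mean -0.00735 against 0.000927 for other pairs), so no pairing by number held throughout. Between CAC and NCAC the same-number mean was 0.115, 0.141 and 0.0654 at 2, 4 and 6 weeks and -0.0838 at 8 weeks. Pairing in single comparisons was therefore not excluded. The preset correlation in camera gave 10, 15, 20 and 18 lists for CAC minus mock at 2, 4, 6 and 8 weeks, 12, 9, 9 and 18 for NCAC minus mock, 14, 13, 17 and 18 for CAC minus NCAC, 19 and 12 for the differences of the CAC and NCAC effects and 10 for mock 8 minus 2 weeks. Without mitochondrially encoded genes, CAC minus mock had 13 genes at 2 weeks and 0 lists at 8 weeks, NCAC minus mock 2 genes at 8 weeks, CAC minus NCAC 0 lists at 4 and 8 weeks, and CAC and NCAC shared 2 genes. Without the 3 libraries farthest on the first component the difference of the CAC effects had 2775 genes. Without the albumin libraries CAC minus mock had 3 genes at 2 weeks and 1 list (interleukin-6) at 4 weeks, NCAC minus mock 0 genes at 2 weeks, the difference of the CAC effects 2845 genes, that of the NCAC effects 0 lists and mock 8 minus 2 weeks 0 genes. Without CAC libraries in the fit NCAC minus mock had 0 genes and 1 list at 2 weeks and 0 genes and 2 lists at 8 weeks, and mock 8 minus 2 weeks 8 genes and 1 list. With each library left out in turn, CAC minus mock ranged over 2 to 37 genes (0 to 1 lists) at 2 weeks, 38 to 241 (0 lists) at 4, 5866 to 7174 (0 lists) at 6 and 7610 to 8444 (0 to 4 lists) at 8 weeks. CAC minus NCAC ranged over 2 to 11 genes (0 lists), 130 to 1494 (0 to 2 lists), 6200 to 7709 (0 lists) and 7580 to 8107 (1 to 4 lists). NCAC minus mock ranged over 0 to 39 genes (0 lists), 0 genes (0 to 1 lists), 0 genes (0 lists) and 0 to 4 genes (0 to 2 lists). The difference of the CAC effects ranged over 3257 to 5263 genes (0 to 1 lists), that of the NCAC effects over 0 genes (0 to 2 lists) and mock 8 minus 2 weeks over 0 to 43 genes (0 lists). Among the genes kept, the gene at the lower quartile had 326 estimated reads, a value that the filter of 1 TPM helps to set. What depth did to genes below the filter was not tested.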

Other observations

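Some gene groups at 8 weeks stood outside the main themes. Nfil3, a repressor of clock output, was 9.68-fold higher in CAC than in mock muscle, and Junb and Klf6, transcription factors induced within minutes of a stimulus, were 8.55- and 4.43-fold higher. The tendon genes that fell were led by the matrix proteoglycan gene Kera (log2 change -1.89, adjusted p = 3.27e-05) and by Tnmd, tenomodulin (-1.40, adjusted p = 0.000301). In the test with limma the change was 2.99 for Nfil3 (adjusted p = 5.74e-07), 2.70 for Junb (adjusted p = 9.17e-09) and 1.97 for Klf6 (adjusted p = 1.84e-07), each higher in 7 of 7 libraries. Of 17 circadian clock genes 9 rose and 2 fell (8 and 2 adjusted over the list alone), which turned to 4 and 5 after rescaling (adjusted p = 0.642 with an estimated correlation). Of 19 immediate-early genes 15 rose (16 adjusted over the list alone, 10 after rescaling, adjusted p = 0.846). Of 13 cell cycle genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, 5 and 3 after rescaling, adjusted p = 0.892). Of 8 tendon genes 5 fell and 1 rose (5 and 1 adjusted over the list alone, 6 lower after rescaling, adjusted p = 0.161).

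Of 15 lymphocyte markers listed 2 were abundant enough to be tested, Ighm and Igkc, and both fell at 8 weeks (2 adjusted over the list alone, 2 after rescaling). Their log2 changes were -3.03 (adjusted p = 5.39e-06) and -1.65 (adjusted p = 0.00233), the latter not called without mock replicate 2 (-0.76, adjusted p = 0.0793). The other 13 markers averaged under 1 TPM over all libraries, a value that stands beside the open strain of the mice.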
